A study of Mus musculus with 79 samples.

How the data were processed

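Libraries of 130 cells each were made from pyramidal, parvalbumin, somatostatin and VIP neurons of the medial prefrontal cortex of 20 male C57Bl/6J mice, found with RNAscope probes and cut by laser, and prepared with a stranded total-RNA kit for picogram input, per the labels' protocols. Each library belongs to 1 neuron type, 1 arm and 1 numbered mouse; a given number is the same animal in every type. Of these 79 libraries, 10 came from each type and arm, except 9 from UCMS PV neurons.

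The values are a signal per gene and library, read counts that the authors divided by a size factor for each library and deposited as normalized counts. HISAT2, SAMtools 1.3 and DESeq2 and the build GRCm38 (mm10) are named in the submitters' processing notes; the read counter, the annotation and whether counting used the strand are not given in the sources used here. Reads of genes that overlap, antisense partners included, and of near-identical copies therefore cannot be told apart. The deposited table held 38879 genes. Of its identifiers, 38636 matched the GENCODE M21 annotation, which supplied gene types and coordinates, and 243 did not; 26 symbols had turned into calendar dates and 183 were blank, and these genes were kept by identifier.

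Dividing each column by the value of 1 read gave whole numbers, within 0.001 reads, for 100% of the values in every library. These recovered reads were used for read totals and for the count tests with edgeR and DESeq2; in SST library U8 the value of 1 read was so near 1 that scaled and unscaled values look alike there. Totals ran from 3642579 to 13529571 reads. A gene with 0 reads in a library can have an expected count of up to 3 reads. Since PCR copies cannot be told from separate molecules in such values, these floors cover counting error only. The SDs and SEs given below come from the spread between libraries or mice. No 2 libraries were identical, and the correlation between libraries ran from 0.528 to 0.848.

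Stress was compared with control within each type by limma-trend with robust empirical Bayes on log2(normalized count + 4), over genes with a mean of at least 10, with Benjamini-Hochberg adjustment at 0.05. Fold changes are differences of means on that scale, where the added 4 shrinks the change of low genes. They can also exceed the ratio of mean counts, or differ from it in sign, where libraries vary widely. Cort in PV neurons had a log2 fold change of 0.66 at mean counts of 73.0 in UCMS and 75.6 in control mice. The average effect used 1 mean per mouse. The difference between types, and each type against the other 3 in the 40 control libraries, kept the mouse as a fixed block, and for the latter a gene also had to differ by 2-fold. Gene lists, 17 of pathways and 11 of cell type markers, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, adjusted over 137 tests, and again with an estimated correlation. Correlations of fold changes were set against 100 relabellings of the mice. Library measures were compared by two-sided permutation tests with 100000 resamples, or all 92378 for PV. These tests, the lists and the alternatives were fixed before the data were examined.

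The genes named were set by rule. For each stress effect they are up to 10 genes per direction past the threshold, or the 5 with the most extreme statistic where fewer than 5 passed; for the difference between types the 10 smallest p; for each type against the others the 6 highest statistics; up to 4 members of each list; and a fixed set of stress, activity and probed genes. Unnamed gene models were counted but not named, and a few genes that met these rules are left out of the text.

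The tests were tested on simulated data with 200 changed genes. At 2-fold and 4-fold, limma recovered 15% and 39% of the changed genes in a simulation of the PYR comparison (16092 genes), 5% and 25% for PV (16847), 8% and 25% for SST (17108), 2% and 24% for VIP (19451) and 25% and 49% for the average (17427). For the difference between types it recovered 2% and 13% (17427 genes), and for SST neurons against the other types 12% and 33%, simulated on the same 17427 genes where the comparison itself used 17498.

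Same-numbered libraries come from the same mouse, so the numbers pair them across types. After removing group means the correlation between 2 libraries of a mouse had a median of 0.00773, against -0.000989 for different mice, and 0 of 117 pairs exceeded 0.1.

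The alternatives were pseudocounts of 1 and 16, no filter or a mean of at least 50, quantile normalization, edgeR, DESeq2, library weights, covariates for genes detected or glial markers, and other treatments of the mouse. Chosen after seeing the data were a covariate for the share of reads on protein-coding genes, scaling to protein-coding reads, leaving out the 7 libraries with the fewest reads, and leaving out each PYR and PV library in turn. On recovered reads edgeR and DESeq2 called 0 and 39 genes for PYR, 0 and 56 for PV, 0 and 54 for SST and 896 and 108 for VIP neurons. The software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, data.table version 1.17.8, Python 3.11.15 and matplotlib 3.10.9.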

Results

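RNA was measured in 4 kinds of cortical neuron from male mice that had lived through 5 weeks of varied mild stressors, called UCMS in the labels, and from unstressed controls. Excitatory pyramidal neurons (PYR) and inhibitory interneurons that make parvalbumin (PV), somatostatin (SST) or vasoactive intestinal peptide (VIP) were found with RNA probes in sections of the medial prefrontal cortex and taken out by laser, 130 cells to a library. The question was which genes differ between stressed and control mice in each kind of neuron. The 79 libraries came from 20 mice, 10 per arm. Mouse U609 of the UCMS arm had PYR, SST and VIP libraries but none from PV neurons, so the UCMS PV group had n = 9 and every other group n = 10. UCMS mice lived singly and controls in groups, so housing differed along with stress in every comparison of the arms. Reads counted on genes ranged from 3642579 to 13529571 per library, and genes with at least 1 read from 9033 to 20307.

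The make-up of the PYR libraries differed between the arms. Protein-coding genes took 64.2% ± 2.26 of the reads in UCMS PYR libraries and 58.7% ± 3.90 in controls (SD, n = 10 each; permutation p = 0.0011, adjusted p = 0.0308 over 28 comparisons of 7 measures in 4 types). Models annotated as microRNA genes took 23.5% ± 2.74 against 29% ± 4.33 (adjusted p = 0.0399), and the 4 most abundant genes 28.5% ± 2.53 against 32.7% ± 3.14 (adjusted p = 0.0399). Genes detected were 15691 ± 1948 in UCMS and 13922 ± 880 in control PYR libraries (adjusted p = 0.0825), at totals of 11.2 ± 1.98 and 11.4 ± 0.701 M reads. In PV libraries, mitochondrial ribosomal RNA, which is made inside the mitochondrion, took 9.41% ± 1.2 in UCMS (n = 9) and 7.92% ± 1.11 in control libraries (n = 10; exact permutation p = 0.0143, adjusted p = 0.0800). That difference did not pass, nor did any other measure of the PV, SST or VIP libraries in its two-sided test (adjusted p from 0.119 upward).

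**Figure D1:**
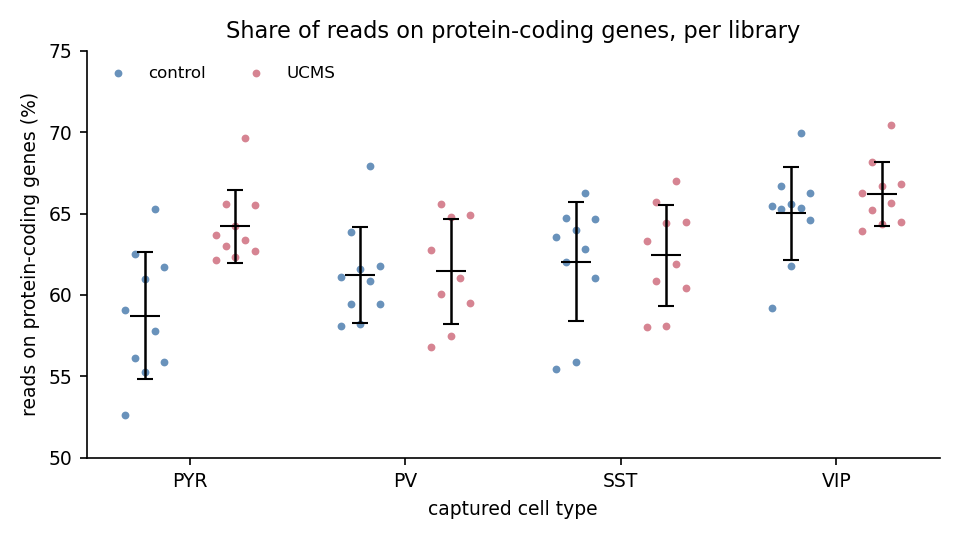
Percent of each library's reads on protein-coding genes, by captured neuron type, for control (blue) and UCMS (red) mice; points are libraries, bars the mean and whiskers the SD. The UCMS PYR libraries averaged 64.2% and the control PYR libraries 58.7%.

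The genes probed to pick the cells marked their own types, which checks the capture and is no finding. In control mice Slc17a7, the vesicular glutamate transporter of excitatory neurons, stood at 14218 ± 2014 normalized counts in PYR libraries (n = 10). It was at 2819 ± 743 in PV, 3262 ± 990 in SST and 4794 ± 1498 in VIP libraries. Pvalb stood at 816 ± 422 in PV libraries and no higher than 37.9 on average in any other type. Sst reached 12981 ± 3745 in SST libraries against at most 260 elsewhere, and Vip 5104 ± 1333 in VIP libraries against at most 35.7.

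**Figure D2:**
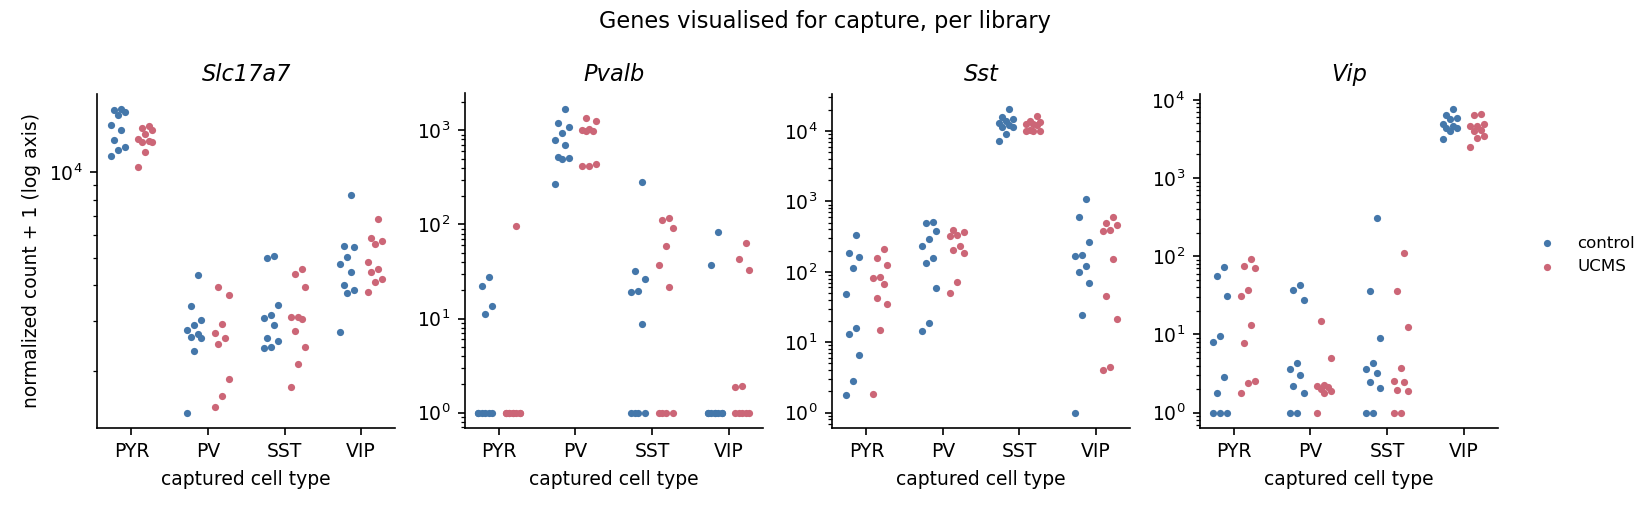
Normalized counts (plus 1, log axis) of Slc17a7, Pvalb, Sst and Vip in each library, by captured neuron type and arm; points are libraries. Each gene was highest in the type it was used to pick. Over both arms together, Slc17a7 was present in the interneuron libraries at 20% to 36% of its mean PYR level.

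To ask what sets each type apart, each was compared with the mean of the other 3 in control mice, with the mouse as a block. In PYR neurons Nptxr, a receptor for neuronal pentraxins at synapses, reached 8721 ± 1201 normalized counts in PYR libraries (n = 10) against 1871 ± 498 in PV, 2890 ± 486 in SST and 5296 ± 1315 in VIP libraries, a log2 fold change of 1.54 (SE 0.105, adjusted p = 1.08e-31). Nell2, a secreted neural glycoprotein, was higher by 1.84 on the log2 scale, Rasgrp1, an exchange factor for Ras, by 1.95, and Olfm1, an extracellular olfactomedin, by 1.15. Bsn, the bassoon scaffold of the presynaptic active zone, was higher by 0.99 (20032 ± 2716 in PYR against 10401 ± 1212 in PV, 10045 ± 1424 in SST and 9832 ± 2036 in VIP libraries) and Kalrn, a signalling protein of dendritic spines, by 0.95. Of 17498 genes, 747 passed adjusted p 0.05 and a 2-fold difference, 392 higher and 355 lower in PYR neurons. Bsn and Kalrn were just short of 2-fold and are not among them.

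In PV neurons Gad1, the main enzyme of GABA synthesis, reached 10316 ± 2029 normalized counts in PV libraries (n = 10) against 212 ± 152 in PYR, 4139 ± 983 in SST and 4245 ± 934 in VIP libraries, a log2 fold change of 2.82 (SE 0.190, adjusted p = 1.97e-14). The channel genes Kcnc1, a potassium channel of fast-spiking cells, and Scn1a, a sodium channel of inhibitory neurons, were higher by 2.00 and 1.89. Atp1b1, the beta subunit of the sodium-potassium pump, was higher by 1.02. PV neurons differed from the other types in 925 of 17498 genes, 449 higher and 476 lower, and edgeR on the recovered reads called 594.

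In SST neurons Grin3a, a subunit of NMDA-type glutamate receptors, reached 4631 ± 907 normalized counts in SST libraries (n = 10) against 341 ± 165 in PYR, 168 ± 189 in PV and 449 ± 106 in VIP libraries, a log2 fold change of 4.44 (SE 0.395, adjusted p = 7.87e-14). Reln, the secreted protein reelin, stood at 9036 ± 1335 against 307 ± 184, 502 ± 371 and 1151 ± 446 in the same order, higher by 4.36. Gad2, a GABA-synthesizing enzyme, was higher by 2.34, Grik3, a kainate receptor subunit, by 2.11, Satb1, a chromatin organizer of interneurons, by 1.86, and Peg3, an imprinted zinc finger gene, by 0.86. SST neurons differed in 313 genes, 194 higher and 119 lower. Peg3 lay under 2-fold and is not counted.

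In VIP neurons Adarb2, of the family of RNA-editing enzymes, reached 6266 ± 1368 normalized counts in VIP libraries (n = 10) against 97.4 ± 102 in PYR, 76.6 ± 159 in PV and 60.1 ± 132 in SST libraries, a log2 fold change of 8.03 (SE 0.679, adjusted p = 4.01e-22). Htr3a, the ion-channel receptor for serotonin, was higher by 7.78 and Cplx2, a complexin of synaptic vesicle release, by 1.77. Nbea, a trafficking scaffold, and Camk2a, a calcium-dependent kinase better known from excitatory cells, were higher by 0.95 and 0.73 and lay under 2-fold. Camk2a was nearly as high in PYR libraries (10372 ± 1507) as in VIP libraries (12009 ± 1967). It stood lower in PV (5768 ± 995) and SST libraries (6354 ± 1321). VIP neurons differed in 493 genes, 311 higher and 182 lower.

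**Figure D3:**
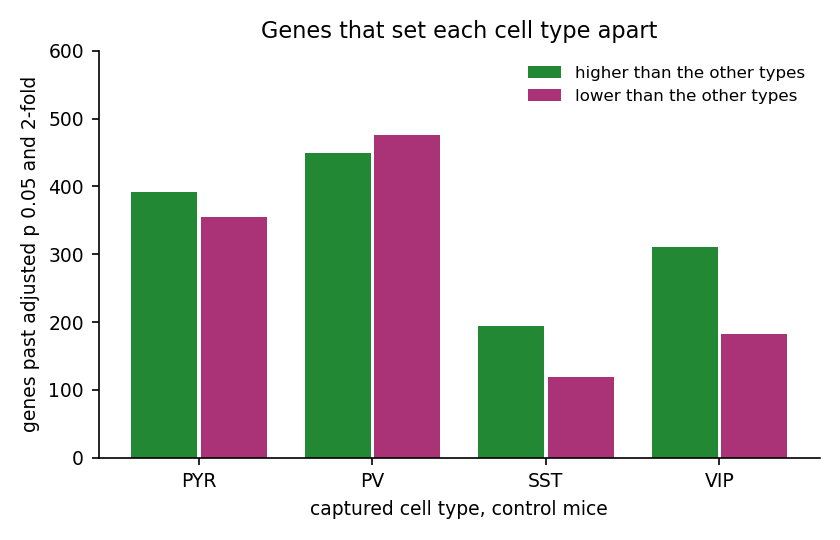
Number of genes past adjusted p 0.05 and 2-fold in control mice for each neuron type against the other 3, higher (green) and lower (magenta). The counts higher were 392, 449, 194 and 311 and the counts lower 355, 476, 119 and 182 in PYR, PV, SST and VIP neurons.

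Stress was then compared with control within each type. In PYR neurons of stressed mice a small set of transcripts fell: bassoon (Bsn), the mitochondrial leucyl-tRNA synthetase (Lars2), 9 gene models for the U1 and U2 small nuclear RNAs of the spliceosome, and Zfpm2, a cofactor of GATA transcription factors. Atp11b, a flippase that moves phospholipids across membranes, rose. Bsn stood at 16511 ± 1960 normalized counts in UCMS and 20032 ± 2716 in control mice (n = 10 each), a log2 fold change of -0.28 (SE 0.0520, adjusted p = 0.00182), and Lars2 at 2288 ± 560 against 3523 ± 874, a log2 fold change of -0.62 (SE 0.120, adjusted p = 0.00189). Both were below the control median in 10 of 10 UCMS mice. Atp11b was above it in 10 of 10, at 1937 ± 356 against 1197 ± 273, a log2 fold change of 0.70 (SE 0.158, adjusted p = 0.0116).

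The small nuclear RNA models moved together. Rnu1a1 fell from 1547 ± 1149 to 677 ± 237 normalized counts (log2 fold change -0.96, SE 0.20, adjusted p = 0.00766, lower in 10 of 10 UCMS mice), and Rnu2-10 from 1503 ± 961 to 708 ± 241 (-0.94, SE 0.197, adjusted p = 0.00766, lower in 9 of 10). The 9 models are near-identical copies, 5 of a U1-type and 4 of a U2-type RNA, so their split of reads is uncertain and they amount to at most 2 separate signals. Small nuclear RNAs took 0.181% ± 0.0640 of the reads of UCMS and 0.366% ± 0.235 of control PYR libraries (n = 10 each; permutation p = 0.0120, adjusted p = 0.0800). Zfpm2 was scattered, at 197 ± 234 against 428 ± 258 (log2 fold change -1.93, SE 0.452, adjusted p = 0.0245, lower in 8 of 10 UCMS mice). Nudt21, a factor in messenger RNA 3' end processing, and Slc4a7, a bicarbonate transporter, had log2 fold changes of 1.36 and 1.76 that did not pass (adjusted p = 0.152 and 0.250), nor did Zfp266 (2.25, adjusted p = 0.233) or Efcab5 (2.83, adjusted p = 0.304).

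In GRCm38 coordinates, the genes called in PYR neurons lie on chromosome 9 from 108096022 to 108190384 (Bsn, ENSMUSG00000032589) and from 123366927 to 123462666 (Lars2, ENSMUSG00000035202), and on chromosome 3 from 35754106 to 35856276 (Atp11b, ENSMUSG00000037400). Rnu1a1 (ENSMUSG00000095969) lies on chromosome 11 from 87422867 to 87423030 and Rnu2-10 (ENSMUSG00000065944) on chromosome 11 from 101658238 to 101658428. Zfpm2 (ENSMUSG00000022306) lies on chromosome 15 from 40655035 to 41104592.

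**Figure D4:**
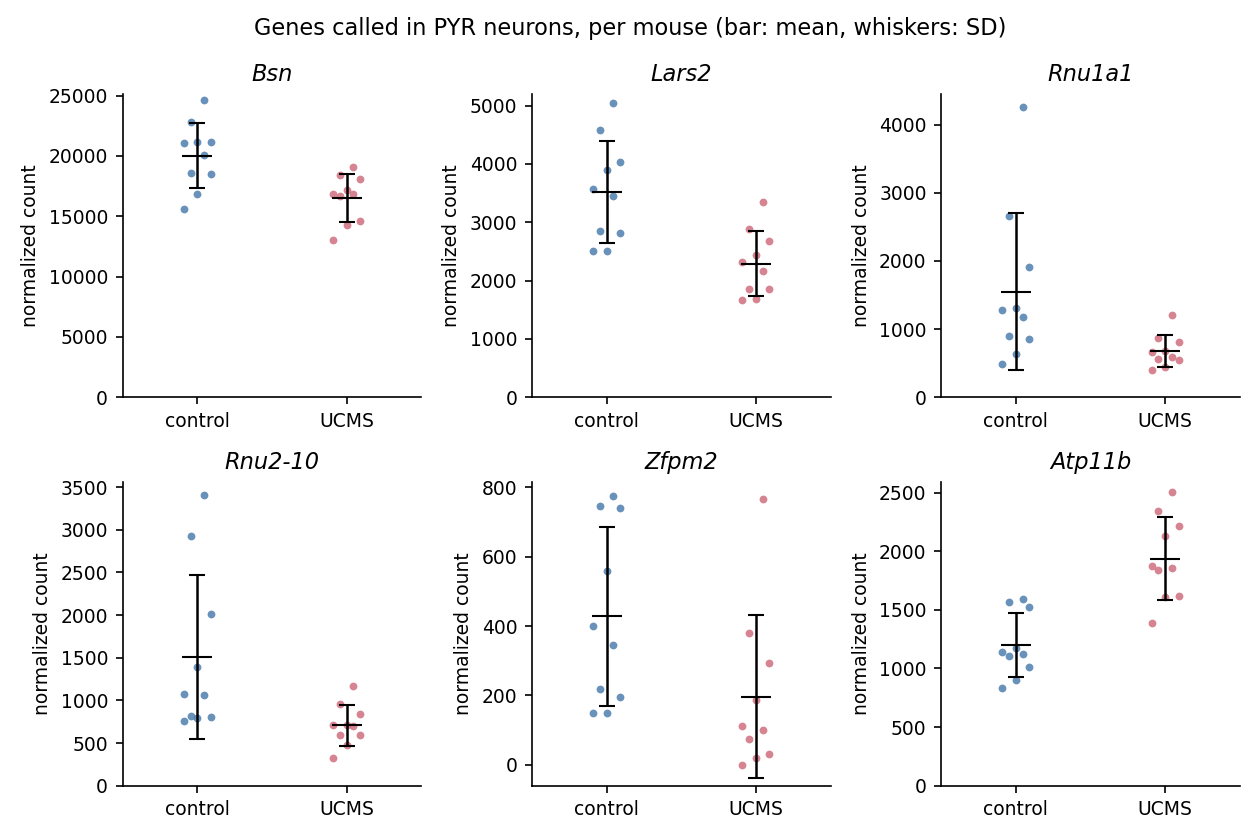
Normalized counts of 6 genes called between UCMS (red) and control (blue) PYR neurons; points are mice, bars the mean and whiskers the SD (n = 10 each). Atp11b was higher in UCMS mice (1937 against 1197), and the other 5 were lower, Lars2 at 2288 against 3523.

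Of 16092 genes tested with limma in PYR neurons, 13 passed adjusted p 0.05, 1 higher and 12 lower in UCMS mice. The count was 0 with all 8 groups in 1 fit and the mouse as a random replicate block, with no filter and at a mean of at least 50. It fell to 2, Bsn and Lars2, without PYR library U3, U6 or U601, and to 5 without U9; with 1 library left out Atp11b was called in 14 of 20 fits and Zfpm2 in 9. It was also 0 with the share of reads on protein-coding genes as a covariate, where the log2 fold change of Bsn was -0.23 and that of Lars2 -0.20. The recovered reads gave 0 calls in edgeR and 39 in DESeq2, which kept Lars2 and Atp11b, and Bsn was not called after quantile normalization (-0.05, adjusted p = 0.977).

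Among the gene groups fixed in advance, cytosolic ribosomal protein genes fell as a list in PYR neurons. Of 75 measured, 53 were lower in UCMS mice, with a median log2 fold change of -0.27 (-0.28 to -0.17 with 1 PYR library left out; camera adjusted p = 1.21e-06 over 137 tests, but adjusted p = 0.184 with an estimated correlation). No single member passed, 0 over all genes and 0 adjusted over the list alone; Rps23 was at -0.56 (SE 0.183, lower in 9 of 10 mice), and Rps3 and Rplp0 at -0.61 and -0.73 were each lower in 10 of 10. These libraries also differed in the share of reads on protein-coding genes (64.2% against 58.7%), and with genes detected as a covariate the list no longer passed (adjusted p = 0.0855).

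The 13 proteins encoded by the mitochondrial genome also fell as a list in PYR neurons, but by a median log2 fold change of only -0.08, with 9 of 13 lower (adjusted p = 0.0440, adjusted p = 0.769 with an estimated correlation), and it was called in 9 of the 20 fits that left out 1 PYR library. mt-Co3, a subunit of cytochrome oxidase, was at -0.31 (SE 0.0924, lower in 9 of 10 mice), and 1 member passed adjusted over the list alone. After quantile normalization this list did not pass (median -0.05, adjusted p = 0.784). Of 24 genes of presynaptic vesicle release, Bsn fell and the other 23 did not pass; the complexin Cplx1 was at -0.47 and Snap25, a fusion protein of synaptic vesicles, at -0.22, while Syp, a vesicle membrane protein, was at 0.19 (list adjusted p = 0.232). Pyramidal markers were mixed, with the deep-layer gene Fezf2 at -0.88, Neurod2 at -0.62 and the upper-layer gene Cux2 at 0.48, none called (list adjusted p = 0.297). Immediate early genes, which respond to activity, gave Jun 0.76, Arc 0.51 and Ier2 -1.01, and neither they nor glucocorticoid-responsive genes passed as lists in any type (adjusted p from 0.475 upward).

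In PV neurons of stressed mice no single gene passed, but marker genes of somatostatin neurons and mitochondrially encoded genes rose as lists, though not with an estimated correlation (adjusted p = 0.496 and 0.758). All 8 measured somatostatin neuron markers had positive log2 fold changes in UCMS PV libraries. Their median was 0.91 (0.51 to 1.26 with 1 PV library left out). The list gave a camera adjusted p = 0.00629, but adjusted p = 0.496 with an estimated correlation. The direction depended on the scale for Cort, whose mean count was lower in UCMS than in control PV libraries. Mean counts of Sst and Tacr1 differed little, while those of Elfn1, Grin3a, Npy, Crhbp and Nos1 were higher in UCMS libraries. Crhbp, which binds corticotropin-releasing hormone, stood at 383 ± 128 against 237 ± 198 normalized counts (log2 fold change 1.69) and Npy, neuropeptide Y, at 254 ± 184 against 115 ± 131 (2.30), each above the control median in 9 of 9 UCMS mice. Both passed adjusted over the list alone and 0 members passed over all genes. Sst itself stood at 241 ± 126 against 229 ± 187 (log2 fold change 0.51), compared with 12981 ± 3745 in SST libraries.

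Of the 13 mitochondrially encoded genes, 12 were higher in UCMS PV neurons, by a median log2 fold change of 0.17 (adjusted p = 0.000504, but adjusted p = 0.758 with an estimated correlation), and 0 passed adjusted over the list alone. mt-Cytb, of respiratory complex III, was at 0.20, mt-Nd1, of complex I, at 0.16, and mt-Atp6, of the ATP synthase, at 0.28. Mitochondrial ribosomal RNA took 9.41% of the reads of these libraries against 7.92% in controls. The list no longer passed without PV library U608 (adjusted p = 0.0743). Microglia markers were higher in 9 of 11 cases, among them P2ry12, a purine receptor of resting microglia (log2 fold change 2.40), and did not pass as a list (median 1.06, adjusted p = 0.0586).

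For single genes in PV neurons, edgeR called 0 and DESeq2 56, of which 46 were detected in at most 4 of the 19 libraries. Limma called 0 of 16847 (630 at an unadjusted p under 0.05, 393 higher and 237 lower, smallest adjusted p = 0.982). The furthest from 0 by the test included Snrpd3, a core protein of spliceosomal particles (log2 fold change 3.33), Map3k1, a stress-kinase activator (2.18), Rnf115 (1.54), Skp1a, a ubiquitin ligase subunit (0.75) and Bbx (1.61) among the higher, and Pacsin2, an endocytosis protein (-0.72), Ddb2, a DNA damage sensor (-3.72), Fam214a (-1.52) and Ctps2 (-1.76) among the lower. Tmed1, a cargo receptor of the early secretory pathway, was listed at 0 in all 9 UCMS PV libraries and at 82.3 ± 141 in controls. With PV library U601 left out, limma called 1 gene, mt-Atp6.

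**Figure D5:**
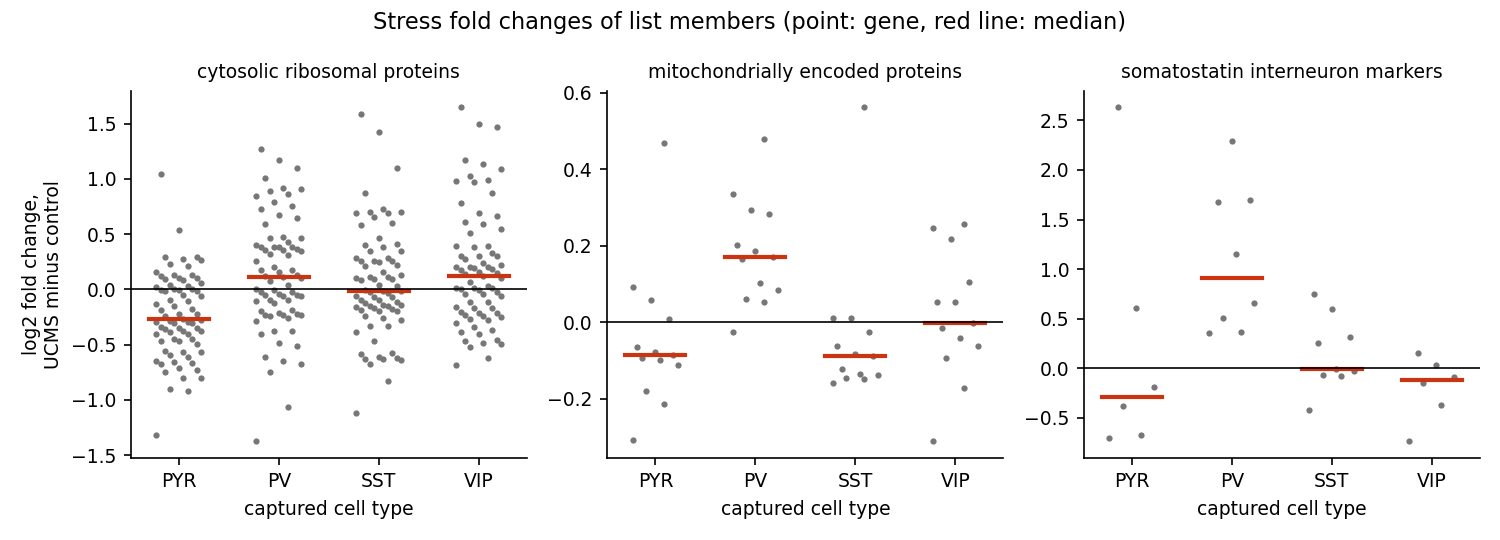
Log2 fold changes, UCMS minus control, of the members of 3 gene lists in each neuron type; points are genes and red lines medians. Ribosomal protein genes lay lower in PYR neurons (median -0.27), and mitochondrially encoded genes (0.17) and somatostatin neuron markers (0.91) higher in PV neurons; quantile-normalized values gave the same direction for each.

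In SST neurons of stressed mice no gene or gene list passed. Nr4a1, an activity-induced nuclear receptor, stood at 385 ± 125 against 188 ± 150 normalized counts (n = 10 each; log2 fold change 1.70, SE 0.537, adjusted p = 0.774), above the control median in 10 of 10 UCMS mice. Hspa5, the main chaperone of the endoplasmic reticulum, was at 0.90 (SE 0.284, 8 of 10 higher), and 22 of 29 genes of the unfolded protein and integrated stress response were higher, with a median of 0.43 (list adjusted p = 0.205); 1 of them passed adjusted over the list alone. Penk, the enkephalin precursor, was at -1.76 and lower in 10 of 10 mice. By the test those far from 0 included Eny2, a transcription cofactor (3.43), Nyap2 (1.33), Haghl (2.18) and Kctd12, a GABA-B receptor auxiliary subunit (3.23) among the higher, and Bicd1, a motor adaptor (-0.85), Nsmce3 (-2.30), Rnu2-10 (-0.78), Blvra (-2.93) and Mast2 (-0.51) among the lower. Limma called 0 of 17108 genes (979 at an unadjusted p under 0.05, 775 higher and 204 lower), edgeR 0 and DESeq2 54. Of the 54, 43 were detected in at most 4 of the 20 libraries.

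In VIP neurons of stressed mice no gene or gene list passed either, and the pan-GABAergic markers were the group nearest to it. Gad1 stood at 3284 ± 720 against 4245 ± 934 normalized counts (n = 10 each; log2 fold change -0.37, SE 0.135, adjusted p = 0.932, lower in 8 of 10 UCMS mice). As a list these markers gave adjusted p = 0.0921, with 6 of 9 lower, a median of -0.13 and a mean of 0.01, so mean and test differ in sign. Fos and Arc, immediate early genes, were at 1.59 and 1.13 and each higher in 8 of 10 mice, and neither passed. By the test the furthest from 0 were Gpm6a, a neuronal membrane glycoprotein (0.52), Bcap31 (3.45), Nup155, a nuclear pore protein (2.37), Cep126 (3.24) and Wars2, the mitochondrial tryptophanyl-tRNA synthetase (3.39) among the higher, and Arnt2, a transcription factor partner (-0.62), Elac2, a tRNA-processing enzyme (-2.23), Vps50 (-1.63), Magi1, a synaptic scaffold (-0.66) and Mical2 (-0.58) among the lower. Limma called 0 of 19451 genes (1001 at an unadjusted p under 0.05, 769 higher and 232 lower), edgeR 896 and DESeq2 108. Of the 896, 836 were detected in at most 4 of the 20 libraries, and of the 108, 94 were.

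Averaged over the 4 types, with 1 value per mouse, no gene or list passed, though genes with a small unadjusted p leaned to the UCMS side. Mcat, an enzyme of mitochondrial fatty acid synthesis, came closest, with a log2 fold change of 2.09 (SE 0.450, adjusted p = 0.152) and higher values in 10 of 10 UCMS mice. Gtf2h1, of a general transcription factor, was at 1.44, Bcap31 at 1.61, Map6d1 at 1.37 and Wars2 at 1.74, and on the lower side Rnu2-10 was at -0.62, Lars2 at -0.28, the transporter Slc12a9 at -1.37, Stac2 at -0.60 and Mast2 at -0.28. The lists nearest to passing were nuclear-retained and non-coding RNAs (6 of 10 lower, median -0.04, mean 0.04, adjusted p = 0.0623) and pan-GABAergic markers (6 of 9 lower, median -0.08, adjusted p = 0.0921). Unfolded protein and integrated stress response genes were higher in 22 of 29 cases, with a median of 0.32 (adjusted p = 0.110); Eif2b1 and Eif2b4, subunits of a translation initiation factor, were at 1.36 and 0.93. Limma called 0 of 17427 genes, with 1189 at an unadjusted p under 0.05, 1055 higher and 134 lower; edgeR and DESeq2 were not run on the average. The median log2 fold change of all genes was itself above 0, at 0.10 in PYR, 0.05 in PV, 0.15 in SST and 0.17 in VIP neurons, and quantile normalization brought it to 0.03, 0.03, 0.07 and 0.06.

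Whether stress acted differently across types was tested in a single model with the mouse as a block. Gene by gene no difference passed: limma called 0 of 17427 genes (816 at an unadjusted p under 0.05), and edgeR called 0. Vps50, a vesicle-tethering protein, came closest, with log2 fold changes of -0.56 in PYR, 0.46 in PV, 1.64 in SST and -1.63 in VIP neurons (adjusted p = 0.655); the next were Mad2l1, Zfp322a, Srpx2, Poln, Zcchc9, Card19, Hykk, Kat8 and Mypopos (adjusted p = 1.00 for the last). The genes called in PYR neurons were not shown to differ between PYR and any other type (adjusted p = 1.00), and Bsn was at -0.01, -0.04 and 0.05 and Lars2 at -0.09, -0.25 and -0.16 in PV, SST and VIP neurons. Atp11b was at 0.38, 0.01 and 0.47, Zfpm2 at 1.05, 0.08 and -0.77, and Rnu1a1 at 0.40, -0.33 and -0.55 in the same order. Rnu2-10 was at 0.20, -0.78 and -0.91.

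Gene lists differed between types at the preset correlation, but none of the differences passed with an estimated correlation (adjusted p = 0.962 to 0.987). Mitochondrially encoded genes differed between PYR and PV neurons by -0.26 (adjusted p = 2.89e-05 over 162 tests) and between PV and SST neurons by 0.22 (adjusted p = 0.000177). Ribosomal protein genes differed between PYR and PV neurons by -0.30 (adjusted p = 0.000595) and between PYR and VIP neurons by -0.40 (adjusted p = 0.0158). Somatostatin neuron markers differed between PV and VIP neurons by 0.97 and between PYR and PV neurons by -0.98 (adjusted p = 0.0119 for each).

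Across genes, which are not independent replicates, the stress fold changes of one type were nearly unrelated to those of another. Pearson's r was highest between SST and VIP neurons at 0.0519 (15618 genes), next between PYR and VIP at 0.0344 and PYR and SST at 0.0221, and lowest between PV and VIP at -0.00564. PYR with PV gave -0.00487 and PV with SST 0.0106. When mice were relabelled between the arms in 100 draws, the mean r was 0.00234 to 0.0230, and no pair passed (permutation adjusted p from 0.280 upward over 6 pairs). The fold changes of single genes were noisy, with a median SE of 0.70 in PYR, 0.80 in PV, 0.76 in SST and 0.80 in VIP neurons. Such noise pulls r toward 0, so a response shared between types is not excluded.

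The genes chosen in advance as stress and activity readouts were not called in any type. Nr3c1, the glucocorticoid receptor, had log2 fold changes of 0.13, -0.04, 0.21 and -0.15 in PYR, PV, SST and VIP neurons. Fkbp5, its chaperone and a standard reporter of its activity, was at -0.30, 0.93, 1.28 and 0.77, each with an SE of at least 0.670. The probed genes gave small values within their own types, with Slc17a7 at -0.13 in PYR, Pvalb at 0.14 in PV, Sst at -0.06 in SST and Vip at -0.22 in VIP neurons, none called. Adjusted over the list alone, 0 of these fixed genes passed; Gad1 in VIP neurons came closest (adjusted p = 0.0676).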

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

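The tests of ribosomal RNA reads at Lars2 and of a trend with expression level and gene length were chosen before their results were seen; the tests of the share of protein-coding reads, of copies, of genes detected, of somatostatin-neuron RNA and of other splits of the mice were chosen after.

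In UCMS PYR neurons the summed count of the 9 small nuclear RNA models was lower by a log2 difference of -0.94 (SE 0.315). Lars2 was lower by -0.62 (SE 0.156), and these libraries had 5.49 percentage points more reads on protein-coding genes. In the other 3 types, where libraries of a group vary in that share, its slope predicts a PYR difference of -0.71 (-1.0 to -0.42) for the small nuclear RNAs and of -0.32 (-0.51 to -0.13) for Lars2, and within PYR at an equal share the differences were -0.47 (SE 0.405) and -0.20 (SE 0.156). The 9 models formed 2 sets, with correlations of 0.974 to 0.998 inside a set and up to 0.889 between the sets. Copies may share reads, but these correlations do not show it, because models of different sets also moved nearly together. Part of the Lars2 signal may be ribosomal RNA. Lars2 followed the summed level of the 3 ribosomal-RNA-like models over the 20 PYR libraries with group means removed (Pearson r = 0.634, 0.252 to 0.845, permutation p = 0.00407). Spearman rho was 0.635 (permutation p = 0.00505), and Pearson r was 0.530 without the 2 farthest libraries. The ribosomal-RNA-like models were lower in UCMS PYR libraries by -0.34 (SE 0.0961). One of them alone averaged 1325630 normalized counts in PYR libraries, so this test and that of the protein-coding share may overlap. For Lars2 the make-up of the libraries is therefore a candidate explanation of part or all of the difference. For the small nuclear RNAs in PYR neurons the make-up and an effect of stress or single housing cannot be told apart, because the SE at an equal share is nearly as large as the difference left. In SST and VIP libraries the protein-coding share differed between the arms by 0.38 and 1.18 points. Rnu2-10 was lower there too, at -0.78 and -0.91, and Rnu1a1 at -0.33 and -0.55, none called. In PV libraries, where the share differed by 0.22 points, they were higher, at 0.20 and 0.40. Whether the share accounts for the values in these types was not tested.

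Ribosomal protein genes in UCMS PYR neurons had a median log2 fold change of -0.27, below all 10000 lists matched on mean expression and exon length (percentile 0, most of those from -0.10 to 0.08), which argues against a trend with level or length. The list lay below all other genes by -0.40 (SE 0.101), and by -0.22 (SE 0.0895) at an equal number of genes detected, so the number of genes detected may account for part of it. All other genes were themselves higher in UCMS PYR libraries by a mean of 0.16 (SE 0.0672), so the -0.40 is not a fall of the list alone. What is left and the number of genes detected cannot be told apart, since genes detected averaged 15691 against 13922 in the arms (adjusted p = 0.0825), a difference that did not pass, and the correction ended the list's call. Of 100 splits of the mice, 1, the real one, gave this list a p as small, but 19 gave one as small (8.83e-09; smallest of any other split 1.72e-20) in some of the 137 list tests from which this list was picked, so chance cannot be excluded. An effect of stress or single housing on these genes stays open and untested.

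Somatostatin neuron markers in UCMS PV neurons were higher by a mean log2 difference of 1.09 (exact permutation p = 0.0227). Stray somatostatin neurons, which the Pvalb probe should have kept out, would bring Sst itself. Its change gives a share of 0.0876% of their RNA, with an upper bound of 1.40%. The other markers need a median of 2.33%, a gap of 2.24 points (0.266 to 8.75). The other 112 genes that are higher in SST neurons differed by 0.14 (SE 0.242, upper bound 0.65, exact permutation p = 0.575). Neither value favours such RNA at the level needed, but the bound of 0.65 leaves part of such a rise open. Splits of the mice gave this list a p as small in 2 of 100, the real one included, but some of the 137 list tests one as small (0.000138) in 78 of 100, so chance cannot be excluded. That stress or single housing raises these genes in PV cells, or that other PV cells were captured, stays a hypothesis, and the list did not pass with an estimated correlation.

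Of 68 groups of libraries and measures, 4 held a library far from the rest, where chance gives about 1 in 20. PYR library U607 of the UCMS arm had 6.15 M reads, the next lowest 10.3 M. PYR library U610 of the UCMS arm had 69.7% of its reads on protein-coding genes, the next highest 65.6%. PYR library U605 of the UCMS arm had 0.334% of its reads on small nuclear RNAs, the next highest 0.203%. VIP library U3 of the control arm had 0.508% on small nuclear RNAs, the next highest 0.275%. Without U607, U610 or U605 the PYR count was 13, 12 and 13.

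Tests of the difference between types set 6 list comparisons apart at the preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.962 to 0.987). Mitochondrially encoded genes differed in their stress response between PYR and PV neurons (adjusted p = 2.89e-05) and between PV and SST neurons (adjusted p = 0.000177). Ribosomal protein genes differed between PYR and PV neurons (adjusted p = 0.000595) and between PYR and VIP neurons (adjusted p = 0.0158). Somatostatin neuron markers differed between PV and VIP neurons (adjusted p = 0.0119) and between PYR and PV neurons (adjusted p = 0.0119).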

How the results depend on the processing

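The covariate for the share of protein-coding reads, scaling to those reads, leaving out the 7 libraries with the fewest reads and leaving out each PYR and PV library in turn were chosen after the results were seen.

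The 13 PYR calls were kept or nearly kept with a pseudocount of 16 (13), quantile normalization (12), library weights (12), the glial covariate (13) and scaling to protein-coding reads (13). They moved to 7 with a pseudocount of 1, and to 0 with no filter and with a mean of at least 50. With genes detected as a covariate 5 genes were called, of which 2 were among the 13. The 13 calls moved to 0 with the share of protein-coding reads as a covariate. With edgeR they moved to 0, while VIP moved from 0 to 896 (573 higher, 323 lower) and PV against the other types from 925 to 594 (347 higher, 247 lower, against 449 and 476); edgeR also gave 163 higher and 49 lower for SST and 259 and 71 for VIP against the other types, a stronger lean to higher. With DESeq2, PYR moved from 13 to 39 (26 higher, 13 lower, 2 of the 13 kept), PV from 0 to 56, SST from 0 to 54 and VIP from 0 to 108. Of these DESeq2 calls, 20, 46, 43 and 94 in PYR, PV, SST and VIP neurons were detected in at most 4 libraries. Such genes numbered 448, 1786, 1095 and 2435 among those tested. Why the count models differ from limma and from each other was not tested. The average effect and the difference between types stayed at 0 in every alternative run on them, which for the average included neither edgeR nor DESeq2 and for the difference not DESeq2. UCMS libraries alone gave 878, 1300 (486 higher, 814 lower), 371 (267 higher, 104 lower) and 732 genes for PYR, PV, SST and VIP neurons against the others. The 4 lists moved to 0 with an estimated correlation and to 2 with genes detected as a covariate, and were 6 without the 7 libraries with the fewest reads, 1 of PV and 6 of VIP neurons, with both PV lists kept. Correlations of fold changes near 0 changed sign: PYR with PV to 0.00490 at a mean of at least 50 and to 0.00240 after quantile normalization, and PV with VIP to 0.0164 at a mean of at least 50 and to 0.000613 as Spearman rho. The cause was not tested. For the named genes, 42 of 7517 alternatives lost a call, 7 gained a call and 0 reversed a call, while 105 for uncalled genes had the other sign; Bsn shrank to -0.05 after quantile normalization.

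With 8 groups in 1 fit and the mouse as a random replicate block (consensus correlation 0.00658), PYR moved from 13 to 0 and PV from 0 to 1; the cause was not tested. The blocked fit changed no other call, and dropping the block from the comparison of types gave 712, 906, 295 and 463 genes for PYR, PV, SST and VIP neurons.

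Leaving out 1 library at a time gave 2 to 14 genes in PYR neurons, 0 to 1 in PV neurons and 2 to 5 lists. The count was 2 without PYR library U3, U6 or U601, when Bsn and Lars2 alone remained. These 2 genes and the ribosomal list in PYR neurons were called in all 20 fits, and the somatostatin marker list in PV neurons in all 19, while the mitochondrially encoded list was called in 9 of 20 for PYR and 18 of 19 for PV.

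Depth limits what low genes can show: 0 reads in a library are compatible with an expected count of up to 3, and the libraries ran from 3642579 to 13529571 reads. Alternatives not run were counting again from the reads with the strand known, a removal of PCR copies, and a model with hidden factors.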

Other observations

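The tests of gene lists between neuron types and the members named from them were chosen after the results were seen. So were the counts over other splits of the mice and over shuffled type labels, apart from the splits for the edgeR count in VIP neurons.

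In control mice the types differed in whole groups of genes that the lists fixed in advance describe. PV neurons were rich in voltage-gated channels: of 20 measured, 9 were higher and 2 lower by at least 2-fold (camera adjusted p = 1.44e-14 over 112 tests, adjusted p = 3.84e-08 with an estimated correlation), among them Kcna2, an axonal potassium channel, at 6439 ± 1084 normalized counts in PV against 2306, 3677 and 1802 in PYR, SST and VIP libraries (n = 10 each), a log2 fold change of 1.41. Energy genes went with them: 9 of 13 mitochondrially encoded genes were higher in PV neurons at any fold (median 0.45, adjusted p = 4.40e-14, adjusted p = 0.00676 with an estimated correlation), and 6 of 77 nuclear-encoded genes of oxidative phosphorylation were higher by at least 2-fold (median 0.70, adjusted p = 1.04e-10). The same nuclear list was lower in VIP neurons (5 lower, median -0.51, adjusted p = 1.49e-09). Receptors divided the types as well: SST neurons were higher in 4 of 22 glutamate receptor genes (adjusted p = 4.13e-07), while PV neurons were lower in 7 and higher in 2 (adjusted p = 0.000507), with Grm7, a presynaptic metabotropic receptor, at -2.65. In the GABA receptor family PV neurons carried more Gabrd (3.58) and less Gabra2 (-2.75).

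Activity and peptide genes also followed cell type. Immediate early genes were higher in PYR neurons, 5 of 21 by at least 2-fold (median 1.40, adjusted p = 2.43e-05, adjusted p = 0.00821 with an estimated correlation), with the nuclear receptor Nr4a3 at 472 ± 176 normalized counts against 68.5, 144 and 159 in PV, SST and VIP libraries, and the transcription factor Egr4 at a log2 fold change of 2.56. Bdnf, a growth factor of excitatory cells, was higher in PYR neurons by 3.82. The 21 neuropeptide genes went up as a list in VIP neurons (4 higher and 1 lower by at least 2-fold, adjusted p = 0.00179, adjusted p = 0.0156 with an estimated correlation), with Tac2, the neurokinin B precursor, at 6.47 and Penk at 5.08. They went down in PV neurons (1 higher, 6 lower, adjusted p = 0.0109, adjusted p = 0.0438 with an estimated correlation) and in PYR neurons (3 higher, 7 lower, adjusted p = 0.00571, adjusted p = 0.0271 with an estimated correlation). In SST neurons they were mixed (6 higher, 2 lower, median -0.03, adjusted p = 0.0150, but adjusted p = 0.0535 with an estimated correlation), with Npy at 5.72 and Pdyn, the dynorphin precursor, at 5.69. Genes tied to corticosteroid signalling were higher in VIP neurons, 2 of 16 by at least 2-fold (adjusted p = 0.0248, but adjusted p = 0.0595 with an estimated correlation). These were Zbtb16, a glucocorticoid-induced transcription factor, at 2173 ± 741 against 648, 494 and 373 in PYR, PV and SST libraries, and Nr3c2, the mineralocorticoid receptor, at a log2 fold change of 2.07. In SST neurons the same list was lower (1 by at least 2-fold, median -0.62, adjusted p = 0.00660, adjusted p = 0.0245 with an estimated correlation).

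Other splits of the mice into arms of the same sizes, 100 with the real one, bear on the stress counts. The 13 genes called in PYR neurons were reached in 2 of 100 splits, the real one included, with 14 in the highest other. Such a count was thus rare but arose by relabelling alone, and 9 of the 13 are copies that move together, so chance cannot be excluded. The counts of 0 in PV, SST and VIP neurons, for the average and for the difference between types are reached by any split (100 of 100, with 5, 2, 3, 2 and 4 genes in the highest others), so the splits do not test them. For each type against the others, the 100 draws instead shuffled the type labels within each control mouse. The real labels gave 747, 925, 313 and 493 genes in PYR, PV, SST and VIP neurons. Each count was reached in 1 draw, the real one, with 26, 4, 31 and 26 in the highest others. The cells were picked by type, so large counts were given by the capture and these draws show nothing beyond it. The 4 gene lists called under stress were reached in 52 of 100 splits, with a median of 4 and a highest other of 20, so chance cannot be excluded for the number of lists. A split that calls 20 lists points to a structure of the samples or to correlation within lists above the preset one, which the splits do not separate. The p of the mitochondrially encoded list was reached in 19 of 100 splits in PYR and in 15 of 100 in PV neurons, so chance cannot be excluded for either. The 896 genes edgeR called in VIP neurons were reached in 15 of 60 splits, with 1321 in the highest other, so chance cannot be excluded there either. For the average effect, 1189 genes had an unadjusted p under 0.05, as many as in 5 of 100 splits (highest other 1881), and 88.7% of them were higher in UCMS mice, a lean reached in 3 splits.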
